A study of Mus musculus with 11 samples.

How the data were processed

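RNA from 11 mouse samples was profiled on 2-colour cDNA arrays, 1 array per sample. Per the labels, each sample's own RNA was extracted with Trizol and labelled with Cy3 by direct incorporation during reverse transcription, and a mouse embryo reference RNA was labelled with Cy5. The samples were 4 arrays labelled as melanocyte lines (D6_MEL, NRAS_MEL, HRAS_MEL and Melan A), 2 labelled as fibroblast lines (3T3 and VA_MEF), 4 labelled as organs (Heart, Kidney, Liver and Lung) and VA_475, whose cell type is not in the labels. MEL was read as melanocyte from the series title, and 3T3 and MEF (mouse embryonic fibroblast) as fibroblasts from general knowledge. The descriptions give D6_MEL and NRAS_MEL a shared code, NRAS_MEL with Nras added, and HRAS_MEL another. No group had a replicate array, and the dyes were not swapped.

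The values deposited by the authors are log ratios of the 2 channels, taken as log2, in a table of 15247 probes, with a value for 15170 to 15210 of them per array. The base of the logarithm, the background correction and the normalization within arrays are not given in the sources used here; base 2 was assumed, as is usual for such arrays. A base of 10 would need ratios past the range of a scanner, but natural logarithms are not excluded, and the counts of genes at least 2-fold apart rest on the base. The medians of the deposited columns lay between -0.03 and 0.03, so the columns were centred or nearly so, by a step that is not stated. Their SD lay between 0.733 and 1.02. Signal intensities were not analysed here, so the signal over background behind a ratio is unknown, and the number of arrays limits the precision.

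The direction of the ratio in the value table is not stated either. The sample titles put the sample before the reference, as in HRAS_MEL / Reference. Read as a ratio, that order runs against the direction taken below. A rule set before the data were examined compared each organ's marker list in the array of that label with the other 3 organ arrays; 3 of the 4 medians were above 0 and 1 was below, so that rule gave no direction. A check chosen after seeing the data, which uses no labels, was added. For each of the 4 organ lists, the array farthest from the list's median over the 11 arrays lay below it in the deposited values, by -7.43 for liver, -3.89 for heart, -2.81 for kidney and -6.50 for lung. Organ markers are high in 1 tissue and low elsewhere, so the table was taken as reference over own RNA, and every sign was turned. This direction is likely, not stated; if the table ran the other way, every signed value below would change sign, and the genes that lead each array labelled as an organ would be other ones. The lowest Pearson correlation across genes of any pair of arrays was 0.108.

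Probes were named through the platform's annotation: 9600 had 1 gene symbol, 214 had several and 5433 were not listed there. Of the 9600, 9492 were found by gene number in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols, and 108 kept the annotation's symbol. Probes with several genes or none were left unnamed. No genome was used, so no coordinates are given. Each array was centred on its median, and the probes of a gene were averaged, which gave 7114 genes, 1810 of them with several probes. Comparisons among the melanocyte-line arrays used the 7053 genes with a value on all 4.

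Single arrays were compared as log2 differences, counting genes at least 2-fold apart, with no test and no p-value. Of 24 gene lists, those with enough measured members were described by the median difference and its percentile among 10000 random lists of the same size, matched in 10 bins of the mean over the arrays. A list was called outside the random range beyond the central 95% of those lists, which describes the 2 arrays and is no test of a condition. Classes of arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05). The 3 classes of 10 arrays shared 1 fit, and the RAS comparison used the 4 melanocyte-line arrays alone. Genes needed 3 values in the melanocyte and organ classes and 2 in the fibroblast class. Lines and organs stand in for replicates there, so p-values measure the spread between lines or organs. Gene lists were tested with camera (preset correlation 0.01, and estimated) and fry. For the correlation of 2 differences that share the D6_MEL array, 100 sets of unchanged arrays were simulated, with noise from the spread between probes of a gene alone.

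The lists, the tests, the alternatives and the rule for named genes were set before the data were examined. The rule takes the 10 highest and 10 lowest genes of each single-array comparison, and 10 in each direction shared by both RAS-labelled arrays. It takes 5 per organ, and the 10 largest changes in each direction past the limma threshold without overlap of the classes. Where none passed, it takes the 5 smallest p in each direction, and in each list described the 4 largest differences. Counts without arrays whose marker genes go against their class were added after seeing the data; those arrays were left out and never moved to another group.

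The fits were tested on simulated data with the real genes' means and spreads and 200 changed genes. For RAS-labelled against other melanocyte lines (7053 genes), limma recovered 0% of 2-fold, 0% of 4-fold and 56.1% of 16-fold changes. For melanocyte lines against organs with 4 arrays each (7036 genes), it recovered 27.9%, 68.2% and 89.4%. With 3 arrays each (7044 genes) it recovered 19.1%, 75.8% and 93.9%. For melanocyte against fibroblast lines (7036 genes) it recovered 7.35%, 65.2% and 86.4%. The changed genes were drawn at random from all genes. With 4 arrays each, the spreads hold the arrays labelled Heart and Melan A, whose marker genes go against their class. The recovered shares need not hold for genes in which those arrays stand apart, so 0 calls there would be no evidence of no difference.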

Results

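Transcript levels were measured in 11 mouse RNA samples against 1 mouse embryo reference, to ask, per the series title, how RAS isoforms act in melanocytes. RAS genes encode small GTPases that signal through the MAP kinase pathway. HRAS_MEL and NRAS_MEL are named for RAS isoforms, while D6_MEL and Melan A carry no RAS name. Melan A is an established line of mouse melanocytes, the pigment cells of the skin, and 3T3 is an established mouse fibroblast line. Each group had 1 array and no replicates, so no error can be given for a single array. Each array gave values for 15170 to 15210 of 15247 probes. All values below are ratios of own RNA over reference, taken as log2, in the direction taken as likely from organ marker genes. If the sample titles, which put the sample before the reference, describe the table as deposited, every sign below would turn.

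The RAS genes named by the labels were looked at first. Hras was not among the named genes analysed here. Nras, averaged over 3 probes, stood at 0.09 in NRAS_MEL, 0.18 in D6_MEL and -0.35 in HRAS_MEL, so it was not higher in NRAS_MEL than in D6_MEL. A probe for the mouse gene need not detect an introduced RAS gene. Rras2, a related GTPase measured by 2 probes, stood at 1.97 in HRAS_MEL, 0.42 in D6_MEL and 0.11 in NRAS_MEL.

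Marker genes went against several labels. Genes of the liver list, which includes albumin (Alb) and transthyretin (Ttr), had their highest median in the array labelled Lung, at 2.94, against -3.47 in the array labelled Liver. Genes of the lung list, which includes surfactant protein D (Sftpd), had their highest median in the array labelled Liver, at 4.88, against -1.25 in the array labelled Lung. Genes of the heart list, such as Fabp3 and Nppb, had their highest median in the array labelled Melan A, at 3.17, against -0.20 in the array labelled Heart. The kidney list was highest in the array labelled Kidney, at 2.56, so 1 of the 4 lists was highest under its own label. With the signs as deposited, a count made after seeing the data, 0 of the 4 would be. These lists held 6, 5, 4 and 7 measured genes.

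Hbb-b1, the beta chain of adult haemoglobin, stood at 0.20 in the array labelled Melan A and at -7.77 in the array labelled Heart, against -7.62 in D6_MEL and -2.30 in Kidney. The proliferation list had a median of -1.67 in the array labelled Melan A and -0.10 in the array labelled Heart. Its medians were -0.07 to 0.11 in the 3 MEL-labelled arrays (D6_MEL, NRAS_MEL and HRAS_MEL). Mlph, which links melanosomes to their motor, stood at -0.06 in the array labelled Melan A, 2.94 in the array labelled Heart and 3.18 in D6_MEL. The melanocyte list of 11 genes did not follow Mlph, with medians of -0.17 to 0.29 in the 3 MEL-labelled arrays and -0.32 to 0.36 in the 4 labelled as organs. Of the 31 genes written for that list only these 11 were measured. Mitf, Tyr, Tyrp1, Dct, Pmel, Mlana and Sox10 were not among them, so its medians cannot decide whether an array held pigment cells. Kit stood at -1.09 and Ednrb at -2.79 in D6_MEL. In the array labelled VA_MEF, Mlph stood at 3.06 and the pigment cell gene Rab38 at 3.40. Its fibroblast list, at -2.49, was the lowest of the 11 arrays in the direction taken, but would be the highest with the signs as deposited, so it is no reason by itself to doubt the label. Reading the other genes as high or low rests on that direction too. The closeness of the array labelled Heart to D6_MEL in Hbb-b1 and Mlph does not, nor does the distance of the array labelled Melan A from both. For these reasons the arrays labelled Heart, Melan A, Liver, Lung and VA_MEF are named by their labels throughout. No array was moved to another group.

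**Figure D1:**
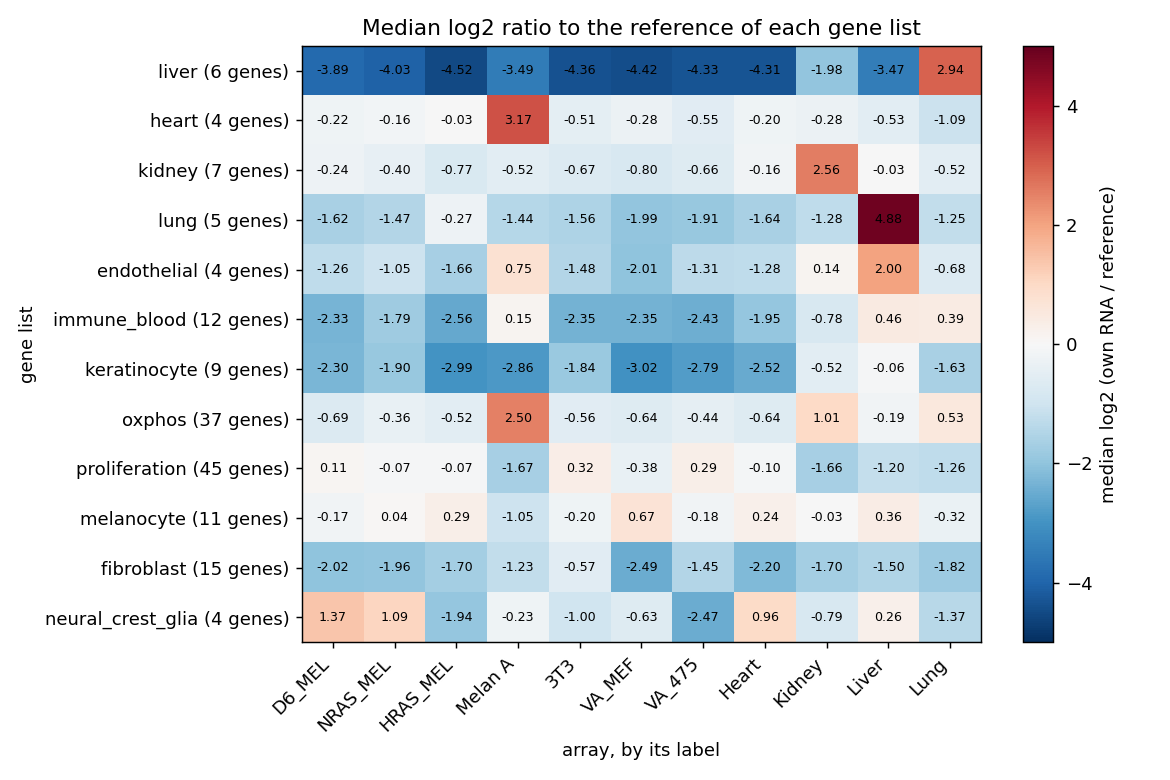
Median log2 ratio of own RNA over reference (colour and printed value) for 12 gene lists (rows, with the number of measured genes) in the 11 arrays (columns, by label). The liver list reaches 2.94 in the array labelled Lung, the lung list 4.88 in the array labelled Liver and the heart list 3.17 in the array labelled Melan A.

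Correlations across genes placed the array labelled Heart beside D6_MEL. Their Pearson r over 7035 genes was 0.922, and 134 genes were at least 2-fold apart. D6_MEL correlated with NRAS_MEL at 0.795 and with HRAS_MEL at 0.646, and NRAS_MEL with HRAS_MEL at 0.717. VA_475 was closest to 3T3, at 0.805. The array labelled Melan A correlated with Kidney at 0.530 and with D6_MEL at 0.238. Genes are not independent replicates, so these values describe the arrays only.

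**Figure D2:**
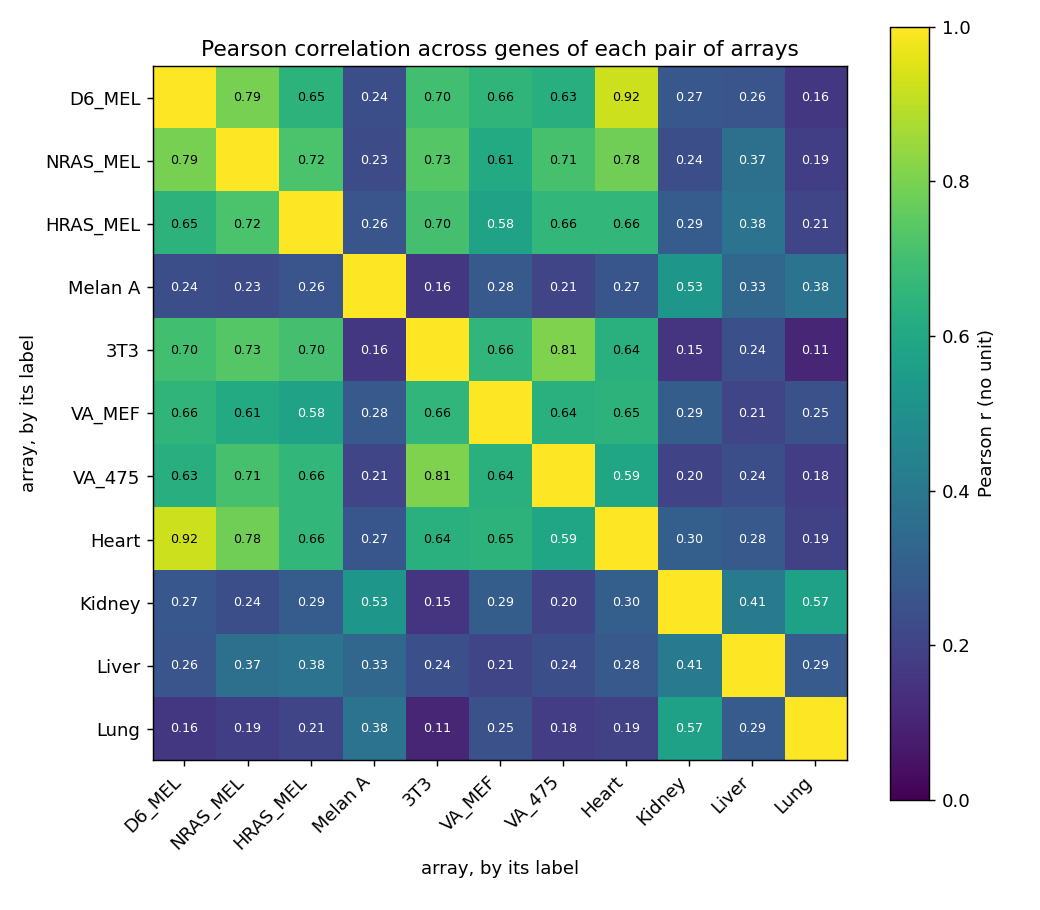
Pearson correlation across 7035 genes (colour and printed value) for each pair of the 11 arrays, named by label on both axes. The highest value, 0.922, joins D6_MEL and the array labelled Heart, and the lowest, 0.108, joins 3T3 and the array labelled Lung.

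NRAS_MEL was compared with D6_MEL, the line with which it shares a description code. The largest differences upward were Crip2 at 4.58, a LIM domain protein, Tmem14c at 3.68, Cttnbp2 at 3.35, Tomm7 at 3.11 and Mgp, an inhibitor of calcification, at 3.07. Lmbr1 at 3.02, the interferon-inducible GTPase Tgtp1 at 2.91, Hba-x at 2.90, Laptm5 at 2.76 and the metallothionein Mt2 at 2.71 followed. The largest downward were the proprotein convertase Pcsk6 at -3.37, Pskh1 at -2.75, Megf9 at -2.58, the sheddase Adam10 at -2.51 and AA792892 at -2.43. Ddx31 at -2.36, the melanoma cell adhesion molecule Mcam at -2.32, Pdlim5 at -2.30, Rab6a at -2.24 and Mcc at -2.21 followed. In all, 479 of 7053 genes were at least 2-fold apart, 170 higher and 309 lower in NRAS_MEL, or 191 and 474 with 1 probe per gene.

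Of 10 interferon-induced genes measured, 5 were at least 2-fold higher in NRAS_MEL than in D6_MEL and 0 were 2-fold lower, with a median difference of 0.72 outside the random range of -0.36 to 0.38, led by Tgtp1, Bst2 at 2.47, Ifitm3 at 2.16 and Stat2 at 1.13. The median was -0.13 against the array labelled Melan A and -0.0604, over 9 genes, against the array labelled Heart, a control chosen after seeing the data here and below. The cholesterol synthesis list of 9 genes had a median of -0.74 (random range -0.39 to 0.43), with Dhcr7 at -1.13, Sqle at -1.03, Lss at -0.89 and Idi1 at -0.74; it was -1.39 against the array labelled Heart and 1.13 against the array labelled Melan A. Ribosomal protein genes had a median of 0.46 over 61 genes (-0.13 to 0.16), with Rps27 at 1.04, Rpl36 at 0.99, Rpl41 at 0.93 and Rps26 at 0.89, and a median of 0.72 against the array labelled Melan A. Oxidative phosphorylation genes had a median of 0.44 over 37 genes (-0.19 to 0.19), with Uqcrc1 at 0.94, Atp5k at 0.94 and Ndufb5 at 0.90, while Atp5a1 lay at -1.20; their median was 0.26 against the array labelled Heart and -2.74 against the array labelled Melan A. The lysosome list had a median of -0.27 over 27 genes (-0.21 to 0.24), with Ctsb at -1.38 and Gusb at -0.97 but Cd63 and Gaa both at 0.82; its median was -0.76 against the array labelled Heart and -0.13 against the array labelled Melan A.

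For some of these genes D6_MEL stood apart from the array labelled Heart, its closest array. Tomm7 stood at -2.0 in D6_MEL and at 0.27 in the array labelled Heart, Lmbr1 at -3.74 and -0.79, and Tmem14c at -2.70 and -0.98. Crip2 was low in both, at -4.54 and -4.62. With the array labelled Heart in place of D6_MEL, an alternative chosen after seeing the data, 642 genes were at least 2-fold apart from NRAS_MEL. Of the 475 genes 2-fold from D6_MEL with values there, 316 were also 2-fold apart in the same direction.

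HRAS_MEL differed from D6_MEL in more genes, with 778 at least 2-fold apart, 365 higher and 413 lower. Cysteine dioxygenase (Cdo1) at 6.36, the IGF-binding protein Igfbp4 at 5.46, the Wnt inhibitor Apcdd1 at 5.29, Myadm at 5.13 and Crip2 at 5.12 were the highest. Biglycan (Bgn) at 4.91, Mgp at 4.87, ceruloplasmin (Cp) at 4.44, the imprinted growth factor Igf2 at 4.13 and Mt2 at 4.09 followed. The lowest were the imprinted gene Mest at -7.09, Nkd2 at -5.37, the intermediate filament nestin (Nes) at -4.81, Dtx1 at -4.52 and the neuregulin receptor Erbb3 at -4.26. Mcam at -4.09, the glucose transporter Slc2a3 at -4.0, Stx16 at -3.88, Gfra1 at -3.60 and Pcsk6 at -3.51 followed.

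Interferon genes were also higher in HRAS_MEL than in D6_MEL, with 7 of 10 at least 2-fold higher and a median of 1.37 (random range -0.43 to 0.36). Bst2 at 3.19, Ifitm3 at 2.58, Irf9 at 2.25 and Tgtp1 at 1.84 led that list, whose median was 0.99 against the array labelled Heart and 0.48 against the array labelled Melan A. Antigen presentation genes of the MHC class I list had a median of 0.53 over 7 genes (-0.49 to 0.44), with Tapbp at 1.58, Tap2 at 1.28, Psme1 at 1.23 and B2m at 0.53; the median was -0.0319 against the array labelled Heart and -0.24 against the array labelled Melan A. Cholesterol synthesis genes had a median of -1.12 (-0.44 to 0.39), and 5 of 9 were at least 2-fold lower, among them Sqle at -1.56, Idi1 at -1.55, Lss at -1.48 and Mvd at -1.25; the median was -1.78 against the array labelled Heart and 0.31 against the array labelled Melan A. The neural crest and glia list of 4 genes had a median of -2.71 (-0.70 to 0.65), from Nes, Erbb3 and Gap43 at -1.16, with Mbp at 0.17; it was -2.19 against the array labelled Heart and -0.55 against the array labelled Melan A.

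Smaller shifts of lists between HRAS_MEL and D6_MEL also lay outside the random range. The invasion list had a median of -0.39 over 22 genes, with Mcam lowest, Plat at -1.36, and Timp3 at 1.76 and Itga3 at 1.52 in the other direction; it was -0.10 against the array labelled Heart and 0.32 against the array labelled Melan A. The keratinocyte list had a median of -0.60 over 9 genes, with Krt18 at -1.29, Sfn at -1.15, Ovol1 at -0.72 and Jup at 0.65; it was -0.00944 against the array labelled Heart and -0.13 against the array labelled Melan A. Oxidative phosphorylation genes had a median of 0.34, with Atp5j at 0.89 and Cox4i1 at 0.78 but Cycs at -1.19 and Cox6c at -0.62. That median was 0.18 against the array labelled Heart and -3.11 against the array labelled Melan A. Ribosomal protein genes had a median of 0.23, with Rpl15 at 1.36, Rpl36 at 1.10, Rpl39 at 0.88 and Rpl38 at 0.82, and a median of 0.60 against the array labelled Melan A. The secreted and inflammatory list had a median of 0.54 but a mean of -0.03, since Pdgfa at -2.23 and Cxcl12 at -1.88 opposed Nfkbia at 1.30 and Il18 at 1.11.

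NRAS_MEL and HRAS_MEL were then set against each other, and 653 genes were at least 2-fold apart, 298 higher and 355 lower in NRAS_MEL. Mest at 5.05, Nes at 4.94, Nkd2 at 4.93, Dtx1 at 4.61 and Stx16 at 4.29 were higher in NRAS_MEL, followed by Pmepa1 at 4.02, Erbb3 at 3.85, Cttnbp2 at 3.52, Zfp979 at 3.48 and Slc2a3 at 3.33. Cdo1 at -6.58, Igfbp4 at -5.17, xanthine dehydrogenase (Xdh) at -4.06, Cp at -3.89 and Ctla2a at -3.70 were lower, followed by Cemip at -3.70, C1ra at -3.66, Plagl1 at -3.65, the collagen gene Col1a2 at -3.63 and Ampd3 at -3.57.

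Targets of MAP kinase signalling had a median of 0.48 over 17 genes in NRAS_MEL minus HRAS_MEL (random range -0.25 to 0.37). Against D6_MEL the list lay inside the random range in both arrays, at 0.23 (-0.26 to 0.34) in NRAS_MEL and -0.31 (-0.38 to 0.30) in HRAS_MEL. In NRAS_MEL minus HRAS_MEL, Plaur at 2.74, the cyclin Ccnd1 at 2.15 and Hmga2 at 1.75 were higher in NRAS_MEL, and Egr1 at -1.62 was lower. The neural crest and glia list had a median of 2.55, with Gap43 at 1.26 and Mbp at -0.32 beside Nes and Erbb3. Cholesterol synthesis genes had a median of 0.53, led by Mvd at 1.68, Idi1 at 0.81, Nsdhl at 0.73 and Lss at 0.58. Interferon genes had a median of -0.50, with Irf9 at -1.82, Igtp at -1.36 and Irf1 at -1.27 but Tgtp1 at 1.07. The MHC class I list had a median of -0.61, with B2m at -1.61, Canx at -0.79 and Psme1 at -0.62 but Calr at 0.72. The lysosome list had a median of -0.22, led by Ctsh at -1.75, Ctsb at -1.32, Naglu at -1.29 and Lamp2 at -1.11. The endothelial list of 4 genes had a median of 0.79, with Esam at 1.03, Emcn at 0.91, Pecam1 at 0.66 and Cdh5 at 0.10.

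Both RAS-labelled arrays departed from D6_MEL in some of the same genes. Of the 7053 genes, 71 were at least 2-fold higher in both, 117 were lower in both and 5 went opposite ways. Independent lists of these sizes would share 8.80 and 18.1 genes, and simulated unchanged arrays with the shared D6_MEL array gave 33.1 and 31.6; that simulation holds only the noise between probes, not the differences between lines. The correlation of the 2 differences was 0.514 and their covariance 0.212, against 0.501 and 0.122 in the simulation. The simulated correlation follows from the shared array whatever the noise, so it is no measure from these data. The simulated covariance and counts rest on a noise SD of 0.376 per array. It came from the root mean square probe spread of NRAS_MEL minus D6_MEL, 0.531, which lies above the median spread of 0.324. With disjoint controls, which bring in the array labelled Melan A, the correlation was 0.0920 in 1 pairing and -0.103 in the other. With 1 control array the controls could not be split, so part of the overlap may come from D6_MEL itself.

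Mt2 and Apcdd1 lay furthest above both D6_MEL and the array labelled Melan A in both RAS-labelled arrays, by at least 2.71 and 2.45. The matrix protein gene Ecm1 followed at 1.88, then Ell at 1.86, Cdk8 at 1.78, Setd1b at 1.53, mesothelin (Msln) at 1.45, Abl1 at 1.41, Lrp1 at 1.41 and Pla2g7 at 1.40. Pcsk6 lay furthest below both, by -3.37. Cnot1 at -1.70, Pdlim5 at -1.58, Slc25a13 at -1.53, the chemokine Cxcl12 at -1.52, Eif2s3x at -1.48, Otud6b at -1.46, Rab6a at -1.38, Add3 at -1.37 and Pank4 at -1.36 followed.

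**Figure D3:**
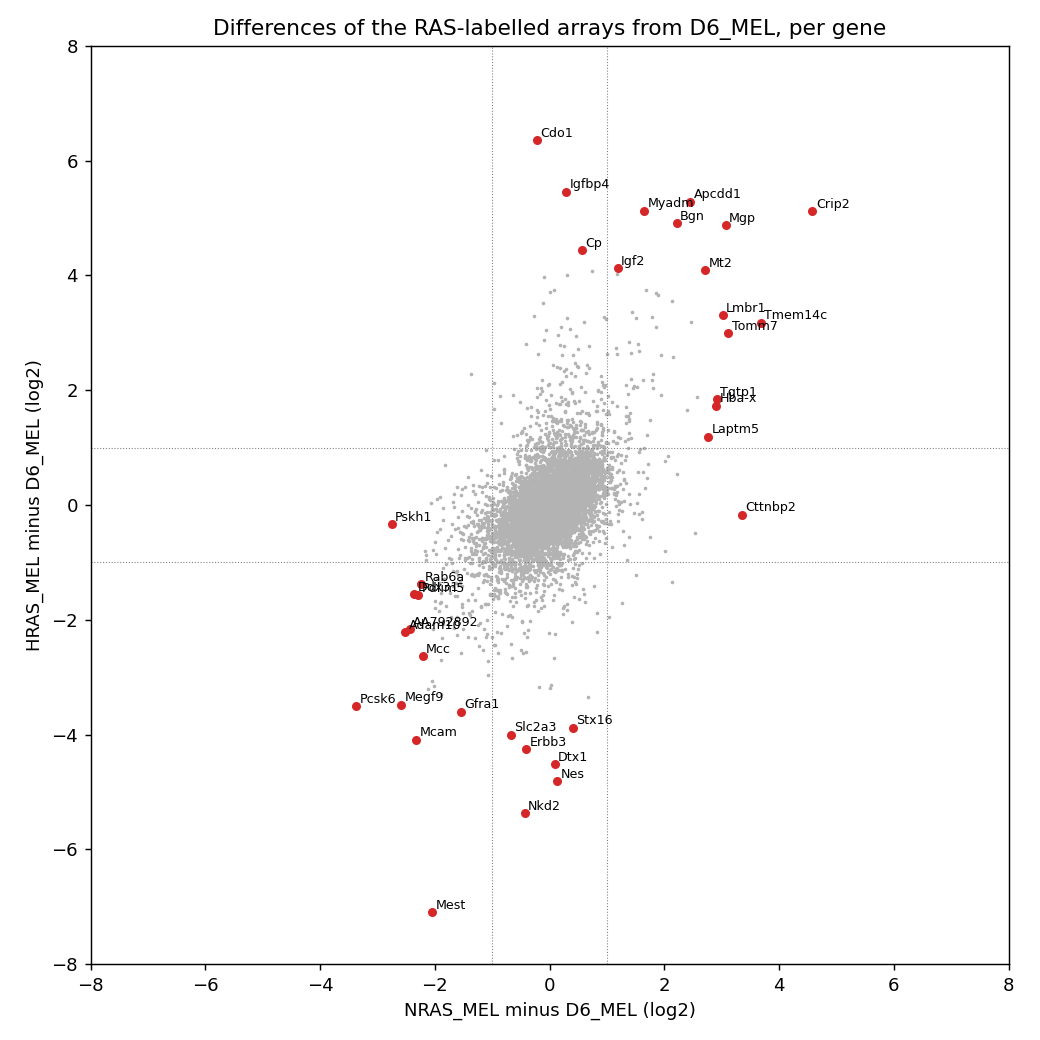
Log2 difference of NRAS_MEL from D6_MEL (x axis) and of HRAS_MEL from D6_MEL (y axis) for each of 7053 genes (grey points), with dotted lines at 2-fold and the named genes in red. Crip2 lies high on both axes (4.58 and 5.12), Pcsk6 low on both (-3.37 and -3.51), and Cdo1 and Nes are apart on the y axis only.

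When the RAS-labelled pair was tested against D6_MEL and the array labelled Melan A, Pcsk6 had the smallest p, with a change of -3.65 ± 0.34 (SE), and failed the threshold with an adjusted p of 0.882 in limma. Ecm1 at 2.35, Mt2 at 4.13, Setd1b at 1.83, Ell at 2.77 and Lrp1 at 1.72 failed too, as did Otud6b at -1.73, Eif2s3x at -1.56, Cnot1 at -2.36 and Add3 at -1.81. Limma called 0 of 7053 genes, with 218 at an unadjusted p under 0.05. Without D6_MEL, which leaves the array labelled Melan A alone on its side, 457 genes passed; without the array labelled Melan A, 0 passed and 312 were under an unadjusted p of 0.05. Camera called 7 of 23 lists, and 0 with an estimated correlation. Oxidative phosphorylation genes had a median of -1.30 (camera adjusted p = 3.105e-06, or adjusted p = 0.743 with an estimated correlation), a list at 2.503 in the array labelled Melan A. Ribosomal protein genes were called up by camera (median 0.52, adjusted p = 5.005e-12), with an adjusted p of 0.743 with an estimated correlation, and 0 of its 61 genes passed, also when adjusted over the list alone.

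D6_MEL and the array labelled Melan A, the pair without a RAS name, were 2-fold apart in 1931 genes, 899 higher and 1032 lower in D6_MEL. The larger side turned with quantile normalization, which gave 955 higher and 889 lower. Mest at 6.59, asparagine synthetase (Asns) at 5.92, Anxa1 at 5.29, Nkd2 at 5.12 and the serine synthesis gene Phgdh at 4.96 were higher in D6_MEL. Psat1 at 4.59, Hmga2 at 4.53, Capg at 4.18, Scd2 at 3.97 and Tes at 3.95 followed. Lipoprotein lipase (Lpl) at -9.44, Crip2 at -7.93, Hbb-b1 at -7.82, Fhl2 at -7.05, Ndrg2 at -7.00 and the sarcomere gene Actn2 at -6.87 were lower, as were Coq8a at -6.59, Lmbr1 at -6.11, Gpx3 at -5.76 and BC053393 at -5.70.

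Oxidative phosphorylation genes had a median of -3.16 in D6_MEL minus the array labelled Melan A, and 35 of 37 were at least 2-fold lower in D6_MEL, led by Atp5a1 at -4.28, Ndufv1 at -4.09, and Cox4i1 and Uqcrc2, both at -4.03. The heart list had a median of -3.87, with Fabp3 at -5.05, Nppb at -4.05, Atp2a2 at -3.68 and Myl4 at 0.55. The blood and immune list had a median of -2.87, with Laptm5 at -3.81, Alas2 at -3.75 and C1qa at -3.68. The endothelial list had a median of -2.0, with Pecam1 at -3.18. Of 44 proliferation genes, 31 were at least 2-fold higher in D6_MEL, with a median of 1.82 and Cdc20 at 2.98, Plk1 at 2.94, Racgap1 at 2.89 and Cdk1 at 2.83. The melanocyte list had a median of 1.03 over 11 genes, with Mlph at 3.24, Hps4 at 1.55 and Hps1 at 1.49 but Ednrb at -1.62.

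The 4 arrays labelled as melanocyte lines were compared with the 4 labelled as organs. Prkab2, a subunit of the energy sensor AMPK, had the smallest p, with a change of 1.12 ± 0.21 (SE), and failed with an adjusted p of 0.930 in limma. B3galt5 at 1.29, Bzw2 at 1.53, Uck2 at 0.67, Klhl23 at 0.83, Tmem59 at -0.95, Vamp8 at -1.31, Raly at -1.36, Dhrs3 at -2.22 and Gsr at -1.33 failed too. Limma called 0 of 7064 genes, with 291 at an unadjusted p under 0.05. Camera called 13 of 23 lists, and 0 with an estimated correlation (smallest adjusted p = 0.404). Without the array labelled Heart 7 genes passed, and without both that array and the array labelled Melan A 150 passed.

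In that smaller comparison, chosen after seeing the data, D6_MEL, NRAS_MEL and HRAS_MEL were set against the arrays labelled Kidney, Liver and Lung. D6_MEL and NRAS_MEL share a description code, so they may not be independent lines. The spread between lines may then be understated and the p-values below too small. Phgdh, which starts serine synthesis, was higher by 4.21 ± 0.42 (SE, adjusted p = 0.00873 in limma). The galectin Lgals1 at 3.95, the chromatin protein Hmga2 at 3.90, Fgf22 at 3.88, Usp36 at 3.87 and Asns at 3.85 were higher as well, as were Prmt8 at 3.73, Matn2 at 3.36, Gpc1 at 3.30 and Capg at 3.23. The carboxylesterase Ces1d was lower by -6.17 ± 0.43 (SE, adjusted p = 0.00332 in limma). Hbb-b1 at -6.08, Ces1f at -5.73, the complement inhibitor Serping1 at -5.23, Spint2 at -4.83 and Rarres2 at -4.65 were lower as well. So were the MHC class II gene H2-Eb1 at -4.25, Lsr at -4.12, Gas6 at -4.06 and the epithelial keratin Krt8 at -3.99. In all, 73 genes were higher and 77 lower in the lines. The rule named only genes with no overlap of the classes, so that lack of overlap is no further support. Chance alone gives it for 10% of genes. The values of Hbb-b1 were among the reasons to doubt the 2 arrays left out, so its call is not independent of that choice. For the same reason no call is given for the proliferation and the blood and immune lists.

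Camera called 8 of 23 lists, those set aside among them, and 0 with an estimated correlation. Oxidative phosphorylation genes (median -0.95), ribosomal protein genes (0.56), MAP kinase targets (0.67) and the invasion (0.79) and endothelial (-1.87) lists were among them. Oxidative phosphorylation genes stood at 2.503 in the array labelled Melan A, which was left out after seeing the data. Their call may thus not be independent of that choice. The keratinocyte list was called too, but it is not particular to keratinocytes, as it holds the epithelial keratin Krt8. Of its 9 genes 2 were lower, Krt8 and E-cadherin (Cdh1) at -2.89, and 5 when adjusted over the list alone (camera adjusted p = 1.372e-04, or adjusted p = 0.345 with an estimated correlation). The count of 150 fell to 2 without D6_MEL, 14 without NRAS_MEL, 39 without HRAS_MEL and 53 without Kidney, and was 652 without the array labelled Liver. It was 93 when the 2 classes were fitted without the fibroblast arrays.

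**Figure D4:**
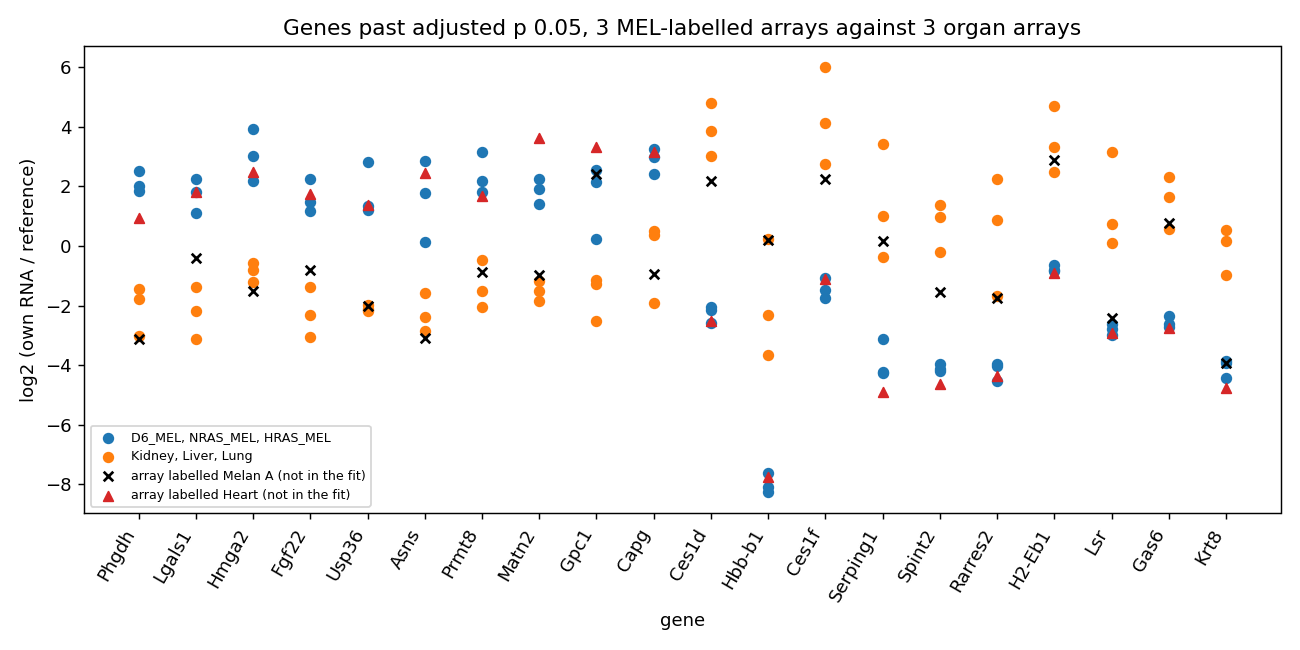
Log2 ratio of own RNA over reference (y axis) of the 20 named genes (x axis) in the 3 MEL-labelled arrays (blue), the arrays labelled Kidney, Liver and Lung (orange), and the arrays labelled Heart (red triangles) and Melan A (black crosses), which were not in the fit. Hbb-b1 stands at -7.77 in the array labelled Heart and at 0.20 in the array labelled Melan A.

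Against the 2 arrays labelled as fibroblast lines, Prkar1a, a regulatory subunit of protein kinase A, had the smallest p, with a change of 1.48 ± 0.25 (SE), and failed with an adjusted p of 0.535 in limma. Nt5dc1 at 2.04, Ddx58 at 1.62, Cst3 at 2.48, Spsb1 at 1.77, Serpinb9b at -1.68, Cxcl1 at -1.37, Slc20a1 at -1.36, Tasor at -1.63 and Wdr43 at -1.17 failed too. Limma called 0 of 7064 genes, with 344 at an unadjusted p under 0.05. Camera called 4 lists, and 0 with an estimated correlation (smallest adjusted p = 0.882). Leaving out 3T3 or the array labelled VA_MEF left 1 array on the fibroblast side, so the other classes alone supplied the spread. Counts from those fits decide nothing about the fibroblast lines and are not given.

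Among the 4 arrays labelled as organs, each had genes at least 2-fold above the other 3. The array labelled Kidney had 158, led by Miox at 5.66 above the next array, Tmem174 at 5.17, Wfdc15b at 5.16, the endocytic receptor Lrp2 at 4.92 and Hsd3b4 at 4.43. The array labelled Liver had 244, led by Cbr2 at 7.38, Sftpd at 7.0, Lyz2 at 5.71, Slc34a2 at 5.42 and Spock2 at 4.61. The array labelled Lung had 246, or 155 after quantile normalization, led by Alb at 8.75, Mat1a at 7.04, Serpina1e at 6.71, Mbl2 at 6.62 and Mark3 at 6.60. The array labelled Heart had 287, led by Mest at 5.49, Matn2 at 4.78, Gpc1 at 4.48, Asns at 4.03 and Nkd2 at 3.85. These counts rest on the direction taken for the ratio: with the signs turned, a count made after seeing the data, 31 other genes would lead in the array labelled Kidney, 61 in Liver, 126 in Lung and 300 in Heart. Sftpd is a surfactant protein of the lung, and Alb and Mbl2 encode plasma proteins made by the liver.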

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

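The tests in this part were chosen after the results were seen, except the counts of list medians that stand apart within a class. Of 48 pairs of a gene list and a class of 4 arrays, 6 had an array whose gap to the others was beyond Dixon's 95% value, and chance gives about 5% of groups. In the melanocyte-line class the array labelled Melan A stood apart in the proliferation list at -1.67, in oxidative phosphorylation genes at 2.503 and in the heart list at 3.17. HRAS_MEL stood apart in the lung list, at -0.27 against -1.62 to -1.44. Among the organ arrays, Kidney stood apart in the kidney list at 2.56 and the array labelled Liver in the lung list at 4.88.

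The arrays labelled Heart and Melan A carried each other's class of genes. On the 73 genes higher in the 3 MEL-labelled arrays than in the other 3 organ arrays, chosen without these 2 arrays, the median position of the array labelled Heart was 0.940 on a scale from 0 (organ mean) to 1 (MEL mean), and that of the array labelled Melan A was -0.0658. A melanocyte-line RNA with heart RNA mixed in would keep such genes at a middle position, which the value of -0.0658 argues against, although on the 77 genes lower in the lines that array stood at 0.410. Wrong labels on both arrays are consistent with these positions, and the identity of the RNA on either was not tested. No biological explanation was tested.

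The arrays labelled Liver and Lung carried each other's markers. The lung list reached 4.88 in the array labelled Liver, the highest of the 11 arrays in the direction taken, and the liver list was highest in the array labelled Lung. Exchanged labels stay open, since these values are the ones that raised that explanation. Mixing of the 2 RNAs would raise each list under its own label too, but the larger of those differences from the MEL-labelled arrays was 0.68. No biological explanation was tested.

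HRAS_MEL lay further from D6_MEL than NRAS_MEL did, by a ratio of 1.62 in genes at least 2-fold apart. With 1 probe per gene the counts were closer, at 919 for HRAS_MEL and 665 for NRAS_MEL. Against the array labelled Heart they were 803 and 642. Against the array labelled Melan A the order turned, at 1856 and 2032. More noise between the probes of HRAS_MEL would spread the probes of a gene further apart, but that spread was 0.892 times the one of NRAS_MEL minus D6_MEL. Over genes with several probes on all 3 arrays the ratio was 0.890, with a bootstrap interval of 0.833 to 0.938. Probes of a gene share the RNA and the labelling of their array. An error common to them would not widen that spread, so the ratio cannot decide about such noise. Another line of origin cannot be told apart from the RAS isoform, since the labels give HRAS_MEL another code than D6_MEL and NRAS_MEL and no array of its parent line was given. The isoform itself stays open and untested.

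For melanocyte lines against organs with 4 arrays each, the real split called 0 genes. Each of the 35 splits of the 8 arrays must give at least as many, so the count decides nothing about chance. The highest of the other splits called 630 genes, and it exchanged the arrays labelled Heart and Melan A, which points to a structure of the samples. With 3 arrays each, 1 of the 10 splits gave as many as the real 150 genes and the highest other gave 0; 10 splits are too few for a share under 0.05.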

How the results depend on the processing

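The alternatives that use the array labelled Heart or leave out doubted arrays were chosen after seeing the data. With the array labelled Melan A as control, 2032 genes were 2-fold apart from NRAS_MEL (479 from D6_MEL) and 1856 from HRAS_MEL (778). That control also turned the sign of list medians: for NRAS_MEL, interferon to -0.13, cholesterol synthesis to 1.13 and oxidative phosphorylation to -2.74; for HRAS_MEL, invasion to 0.32, MHC class I to -0.24, cholesterol synthesis to 0.31 and oxidative phosphorylation to -3.11. With the array labelled Heart as control, interferon turned to -0.0604 for NRAS_MEL and MHC class I to -0.0319 for HRAS_MEL. The correlation of the RAS differences moved from 0.514 to 0.0920 and -0.103 with disjoint controls. The marker genes of that array give a reason to doubt it as a control, but the cause was not tested.

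Leaving out each array in turn gave 0 to 457 genes for the RAS comparison, 0 to 7 for lines against organs and 0 to 4 for lines against fibroblast lines. Without the arrays labelled Heart and Melan A, lines against organs gave 150; leaving out 1 more gave 2 to 652, and fitting the 2 classes alone gave 93, with fewer arrays to estimate the spread. Quantile normalization lowered the count of the array labelled Lung from 246 to 155; the cause was not tested. Spearman's rho was 0.637 for D6_MEL and NRAS_MEL, 0.616 for HRAS_MEL and NRAS_MEL and 0.501 for HRAS_MEL and D6_MEL. The 4 counts of genes 2-fold apart stayed within 1.5 times under the other settings run. Of 100 entries of named genes, some genes entered more than once, quantile normalization moved 22 by more than the probe spread and reversed 0. All 22 were in single-array comparisons. Entries of the fit with 3 arrays each were judged by adjusted p and could not be counted as moved. All 32 camera calls missed the threshold with an estimated correlation, and fry kept 3. These were the proliferation, blood and immune and keratinocyte lists, all without the arrays labelled Heart and Melan A. The proliferation and the blood and immune lists are not independent of leaving those arrays out, so that fry kept them is no support. Fry also tests a list against no change, not against the other genes. No paired analysis was possible because each group had 1 array. Signal over background was not analysed here.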

Other observations

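The test of imprinted genes below was chosen after the values were seen. VA_475, whose cell type is not in the labels, had a proliferation list median of 0.29 and a fibroblast list median of -1.45, against 0.32 and -0.57 in 3T3. Its neural crest and glia list stood at -2.47 against -1.0 in 3T3, and its cholesterol synthesis list stood at 0.97 against 0.27. Mlph stood at -0.34 in VA_475 and -0.71 in 3T3. Rspo2, a Wnt agonist, stood at 3.67 in 3T3 and -0.62 in VA_475, and the growth factor Ptn at 0.24 and -3.76.

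The serine synthesis genes Phgdh and Psat1, singled out after their values were seen, stood above 0 in the 3 MEL-labelled arrays, 3T3, VA_475 and the array labelled VA_MEF, and below 0 in the array labelled Melan A. Phgdh stood at 0.70 in VA_475, 1.59 in 3T3, 1.80 in the array labelled VA_MEF and 2.53 in HRAS_MEL, and at -3.10 in the array labelled Melan A. Psat1 stood at 1.67 in 3T3, 1.09 in D6_MEL and -3.50 in the array labelled Melan A, and at 1.29 in the array labelled Heart.

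Imprinted genes were among the largest differences. Mest stood at 1.78 in D6_MEL and -5.31 in HRAS_MEL, Igf2 at -7.36 and -3.23, and Plagl1 at -3.55 and -1.27. Cdkn1c, less than 2-fold apart there at -6.11 and -5.17, stood at 0.37 in the array labelled Liver. A hypothesis is that imprinted genes may differ between these lines more often than other genes. These 4 genes, seen first, were set aside. Of 24 other measured imprinted genes, 5 were at least 2-fold apart between HRAS_MEL and D6_MEL, among them H19 at 2.79 and Dlk1 at 2.03. Random lists matched on mean value gave a median of 4, and 39.1% of them gave as many, so the count lay inside the range of other genes and leaves the hypothesis open.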
